A study of Mus musculus with 14 samples.

How the data were processed

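Total RNA from mouse eyes at postnatal day 1 was measured on 14 single-colour Affymetrix arrays, per the labels after amplification of 50 ng of RNA and labelling with biotin. The labels form 4 groups in 2 experiments. The Snf2h experiment holds 4 wildtype and 4 lens-conditional Snf2h knockout samples on a C57BL/6 background, and the Brg1 experiment holds 3 wildtype and 3 conditional Brg1 knockout samples on a mixed background. The deposited values were probe set intensity on a linear scale, summarised by RMA per the submitters' processing notes, with the RMA version not given in the sources used here. Whether both experiments were processed together is not stated. No detection calls came with the values, so dim probe sets, whose fold changes are compressed by background, were kept. The number of arrays limits the precision of every value. The series text speaks of 4 biological replicate experiments, and the labels do not say from which animals the Brg1 samples came.

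The log2 of the deposited intensities was taken, with no further scaling and no offset. The array held 22690 probe sets, of which 64 controls were left out. The annotation gave 1 gene to 20380 probe sets, several genes to 691 and no gene to 1555, and only the 20380 were used. Symbols were those of the array annotation, and the RefSeq gene table changed 0 of them. No genome build is named in the array annotation, so no positions are given. Each gene was represented by the probe set with the highest mean over all 14 arrays, which gave 12393 genes, 4956 of them with more than 1 probe set.

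Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, each knockout against the wildtype arrays of its own experiment. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The difference between the knockout effects was tested as an interaction contrast over all 14 arrays with 4 group means. Errors of log2 changes are limma's moderated standard errors. Tests were two-sided, except the Fisher exact tests of overlap, which were one-sided. All probe sets of Smarca5 and Smarca4 were tested, with adjustment over all probe sets.

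The 24 gene lists for lens, cell cycle, chromatin, retina, other eye tissue, immune and stress programmes were compared with all other genes by camera with a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance in 1 direction, stood beside it. Some genes are in more than 1 list, so the lists are not independent. The mean change of a list was also tested between arrays with an exact permutation test. Its smallest possible p is 0.0286 for 4 against 4 arrays and 0.1 for 3 against 3, so the Brg1 experiment cannot reach 0.05 in that test.

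The comparisons, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named Smarca5 and Smarca4. It then named the 12 largest rises and 12 largest falls among called genes whose knockout arrays all lay beyond all wildtype arrays, up to 4 members of each described list with the smallest p, the 6 largest differences per direction in the interaction and up to 6 shared calls per direction. Unnamed transcripts were counted but not named. The set of described lists was chosen after the tests.

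On simulated data with 50 changed genes at each size, the test of the Snf2h experiment recovered 56% of genes changed by a log2 of 1 and 88% of those changed by 2. The test of the Brg1 experiment recovered 28% and 72%, and the interaction recovered 26% and 78%. Genes without a simulated change gave 9, 4 and 5 calls. The simulated noise was independent for each gene and array, while Snf2h cKO replicates 1 and 2 were near-identical, so recovery in the real data can differ.

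Alternatives were quantile normalisation of all arrays or within each experiment, a filter on dim probe sets at a log2 level of 6.77 that kept 7229 genes, all probe sets or their mean per gene, trended robust eBayes, array weights, the replicate number as a block, a log2 fold threshold of 1, 1 fit over all arrays, an unmoderated test and leaving out each array in turn. Chosen after seeing the data were averaging near-identical knockout arrays, also in the splits of the samples and in the comparison of muscle with stroma, splits of the Snf2h arrays with the Brg1 groups kept, the Gapdh 3' minus 5' difference and the Xist level as covariates, array weights for the overlap of calls and alternatives for the overlap at unadjusted p. Lists of cornified skin, resident macrophage, neutrophil, wound keratinocyte and lymphocyte markers were also added then.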

Results

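Gene expression was measured in whole eyes of newborn mice after conditional deletion of 1 of 2 chromatin remodelling ATPases. Snf2h, encoded by Smarca5, is an ATPase of ISWI complexes, and Brg1, encoded by Smarca4, is an ATPase of SWI/SNF complexes. The Snf2h experiment compared 4 lens-conditional knockout (cKO) with 4 wildtype samples, and the Brg1 experiment compared 3 cKO with 3 wildtype samples. The labels do not say in which cells Brg1 was deleted. Median probe set intensity lay between 101 and 114 on all 14 arrays. No control arrays were shared between the experiments.

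Some arrays stood apart in both experiments. Snf2h cKO replicates 1 and 2 differed across genes with an SD of 0.205 on the log2 scale, while the other 17 pairs of arrays within a group gave 0.401 to 0.723. In wildtype replicate 3 of the Snf2h experiment, the 3' probe set of the control transcript Gapdh exceeded its 5' probe set by 4.47 on the log2 scale, against 1.09 to 1.46 in the other 3 wildtype arrays and 0.77 to 0.99 in the 4 knockout arrays. This sign of RNA quality therefore separated the groups of the Snf2h experiment, while the same difference for Actb overlapped (1.44 to 3.08 in wildtype, 1.34 to 1.83 in knockout arrays). Wildtype replicate 3 had a mean log2 level of 7.14 over 18 cornified skin and hair follicle markers, against 3.53 to 4.21 in the other wildtype arrays and 3.40 to 3.68 in the knockout arrays. Xist, the transcript expressed from the inactive X chromosome, was low in wildtype replicates 1 and 3 and in cKO replicates 1, 2 and 4 of the Snf2h experiment. It was low in cKO replicate 1 and high in the other 5 arrays of the Brg1 experiment.

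The transcripts of the deleted genes were examined to see how far deletion lowered them in the whole eye. The Smarca5 probe set 1424205_at was at 70.9% of wildtype in Snf2h cKO eyes, with a log2 level of 9.39 ± 0.27 (SD, n = 4) in wildtype and 8.90 ± 0.14 (SD, n = 4) in knockout eyes. The log2 change was −0.50 ± 0.16 (SE, adjusted p = 0.192 over all probe sets by limma), so it did not pass the test. The other Smarca5 probe sets, 1424206_at and 1424207_at, gave −0.19 ± 0.25 and 0.31 ± 0.25 (adjusted p = 0.712 and 0.539). In Brg1 cKO eyes the Smarca4 probe set 1426805_at was at 59.8% of wildtype (log2 change −0.74 ± 0.30 SE, adjusted p = 0.579, n = 3 against 3), and 1426804_at changed by 0.05 ± 0.22 (adjusted p = 0.972). The Smarca4 probe sets in Snf2h cKO eyes gave 0.89 ± 0.17 (1426805_at, adjusted p = 0.0954) and −0.33 ± 0.22 (1426804_at, adjusted p = 0.457). Whole eyes hold much tissue other than lens, and whether any of these probe sets lies in a deleted exon is not known. Leaving out Snf2h cKO replicate 3 turned the change of 1424206_at to 0.059, and leaving out Brg1 cKO replicate 1 turned that of 1426804_at to −0.14.

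The comparison of Snf2h cKO with wildtype eyes asked which genes depend on Snf2h as lens cells leave the cell cycle and fibre cells mature and lose their nuclei. Of 12393 genes, 1 rose and 1 fell. St14, which encodes the epithelial serine protease matriptase, rose 2.1-fold (log2 level 6.80 ± 0.08 to 7.87 ± 0.13, SD, n = 4 each; change 1.07 ± 0.12 SE, adjusted p = 0.0449) and was higher in 4 of 4 knockout arrays than in any wildtype array. Acsf2, which encodes an acyl-CoA synthetase family member, was 2.98-fold lower (8.76 ± 0.08 to 7.19 ± 0.33; change −1.58 ± 0.17 SE, adjusted p = 0.0449) and was lower in 4 of 4. At an unadjusted p under 0.05 there were 2098 genes (1030 higher and 1068 lower), where 619.7 would be expected by chance, and in 10.3% of genes the groups did not overlap, where chance gives 2.86%. These p values and the 2.86% treat the near-identical cKO replicates 1 and 2 as independent. With this pair averaged as 1 sample, 744 genes were lower at an unadjusted p under 0.05. The count of called genes was then 0, and St14 and Acsf2 both had an adjusted p of 0.209. With quantile normalisation of all arrays only Acsf2 passed (St14 at 0.0526). The count was 60 without wildtype replicate 1, 8 without wildtype replicate 4, 1 without wildtype replicate 2 or 3 or cKO replicate 3, and 0 without cKO replicate 1 or 2, while without cKO replicate 4 it was 2, neither of them St14 or Acsf2. Of 29 genes with an adjusted p under 0.1, a threshold chosen after seeing the data, 13 had other probe sets, and of these 20 probe sets 9 had the same and 11 the opposite sign (0 of the 11 at an unadjusted p under 0.05).

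Genes of the lens fibre, the elongated cell that loses its organelles as it matures, had mostly negative changes in Snf2h cKO eyes, and their lists did not pass the test. Dnase2b, the nuclease that degrades DNA in fibre cell nuclei, had a log2 change of −1.53 ± 0.37 (SE, adjusted p = 0.163), and Hsf4, a transcription factor of fibre differentiation, had −0.86 ± 0.18 (adjusted p = 0.137). Each of these was lower in all 4 knockout arrays than in any wildtype array. Mip, the major membrane water channel of fibres, gave −1.29 ± 0.51 (adjusted p = 0.258) with its other probe set at −0.39. Cryl1 gave 0.61 ± 0.17 (adjusted p = 0.17) with its other probe set at −0.34. Of 23 measured fibre genes other than crystallins, 0 rose and 0 fell over all genes tested, 1 rose and 2 fell adjusted over the list alone, and 18 had negative changes (camera adjusted p = 0.151, mean −0.29 ± 0.19 SE between arrays). Of 14 crystallins, the abundant structural proteins of the lens, 0 were called over all genes or adjusted over the list alone and 12 had negative changes, such as Crygs at −0.41 ± 0.20 and Crygf at −0.36 ± 0.14 (camera adjusted p = 0.167, mean −0.17 ± 0.20). The mean of the fibre list relative to wildtype was −0.55 and −0.58 in the near-identical cKO replicates 1 and 2, 0.01 and −0.04 in cKO replicates 3 and 4, and −0.29 in wildtype replicate 3. The crystallin list passed without wildtype replicate 3 (adjusted p = 0.00194) and without cKO replicate 4 (0.0133). The fibre list passed without wildtype replicate 3 (0.0132), cKO replicate 3 (0.0141) or cKO replicate 4 (0.0457) and with the filter on dim probe sets (0.031). With array weights, which favour the near-identical cKO replicates 1 and 2, the fibre list (0.00654, median −0.13 to −0.28) and the crystallins (0.00192, median −0.17 to −0.35) passed.

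Lists for other steps of lens development did not pass either with equal weight for each array. Of 22 genes of organelle degradation and denucleation, 0 were called over all genes, and 1 rose and 2 fell adjusted over the list alone, with the autophagy gene Atg5 at 0.79 ± 0.18 (adjusted p = 0.158; list camera adjusted p = 0.854). The 2 that fell, Dnase2b and Hsf4, are also in the fibre list. Among 20 lens epithelium genes 0 were called over all genes or adjusted over the list alone, with the lens transcription factor Pitx3 at −0.66 ± 0.19 (adjusted p = 0.184; list 0.324, or 0.0353 with array weights, which took its median from −0.13 to −0.23). Of 27 lens transcription factors 0 were called over all genes, and 1 rose and 1 fell adjusted over the list alone (list 0.905). Those were Tfap2b, also in the list of other retinal neurons, and Hsf4, also in the fibre list. In the cell cycle, the replication genes Mcm10 (−0.63 ± 0.15, adjusted p = 0.163) and Rfc4 (−0.53 ± 0.14, 0.169) had negative changes, as had the cell cycle inhibitor Cdkn1c (−0.59 ± 0.15, 0.163). The 35 genes of DNA replication, 36 of mitosis and 25 of cell cycle exit had 0 calls over all genes or adjusted over the list alone (list camera adjusted p = 0.503, 0.837 and 0.81). At an unadjusted p under 0.05 these 3 lists held 0, 3 and 4 higher and 6, 0 and 2 lower genes.

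Genes of retinal neurons were higher as groups in Snf2h cKO eyes by camera with the preset correlation. In 25 of 35 splits of the Snf2h arrays camera called at least the 4 lists of the real split, so chance cannot be excluded. Of 29 photoreceptor genes, 0 were called over all genes and 4 rose adjusted over the list alone, and 23 had positive changes. Those 4 were Rom1 (0.99 ± 0.27, adjusted p = 0.17 over all genes), a protein of outer segment discs, Otx2 (0.56 ± 0.15, 0.169), a transcription factor of photoreceptor fate, Unc119 (0.51 ± 0.13, 0.163), and Guca1b (0.69 ± 0.15, 0.156), an activator of guanylate cyclase whose other probe set gave −0.14. The list passed with camera (adjusted p = 7.21e-06) but not with an estimated correlation (adjusted p = 0.915 with an estimated correlation). Its mean change was 0.41 ± 0.19 (exact permutation p = 0.0286, the smallest possible), with cKO replicate 4 at 0.89 and the other 3 knockout arrays at 0.21 to 0.33. That p counts the near-identical cKO replicates 1 and 2 as independent. Of 30 genes of other retinal neurons, 0 were called over all genes, and 6 rose and 1 fell adjusted over the list alone. Examples were the synaptic vesicle gene Syt1 (1.45 ± 0.30, adjusted p = 0.135), the GABA-synthesising enzyme Gad2 (1.29 ± 0.24, 0.12) and the amacrine cell transcription factor Tfap2b (1.02 ± 0.18, 0.106). The ganglion cell gene Rbpms gave −0.86 ± 0.17 (adjusted p = 0.122), and its 4 probe sets disagreed in sign. This list had camera adjusted p = 0.004, or adjusted p = 0.558 with an estimated correlation, and it did not pass with the filter on dim probe sets (0.172). The Gapdh 3' minus 5' difference was lower in all knockout arrays (0.77 to 0.99) than in any wildtype array (1.09 to 4.47).

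Stromal genes were lower and chromatin remodelling genes higher as groups in Snf2h cKO eyes by camera with the preset correlation. By the same 25 of 35 splits, chance cannot be excluded for these lists either. Of 31 genes of corneal stroma and periocular mesenchyme, 0 were called over all genes or adjusted over the list alone, and 28 had negative changes (mean −0.37 ± 0.17, exact permutation p = 0.0571, camera adjusted p = 0.000554). The adjusted p = 0.915 with an estimated correlation did not pass. Examples were the collagen cross-linking enzyme Lox (−1.12 ± 0.32, adjusted p = 0.188, with another probe set at 0.16), Aspn (−0.74 ± 0.22, 0.199) and the collagen Col5a2 (−0.65 ± 0.22, 0.213). Of 33 chromatin remodelling subunits, 0 were called over all genes or adjusted over the list alone and 23 had positive changes (mean 0.16 ± 0.07, camera adjusted p = 0.0253). The adjusted p = 0.915 with an estimated correlation did not pass. Chd4, the ATPase of the NuRD complex, gave 1.32 ± 0.36 (adjusted p = 0.17), and Smarcc1, a SWI/SNF core subunit, gave 0.71 ± 0.22 (0.205). The chromatin list did not pass without wildtype replicate 4 (adjusted p = 0.272) or cKO replicate 3 (0.081), with quantile normalisation (0.0938), with the filter on dim probe sets (0.0804) or with array weights (0.196, median −0.01). Nor did any other list in either knockout pass with an estimated correlation or with fry. Without wildtype replicate 2 the stroma median went from −0.36 to −0.55, and Gapdh 3' minus 5' differences separated knockout (0.77 to 0.99) from wildtype arrays (1.09 to 4.47) here too.

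The tests of surface epithelium and immune genes depended on single arrays of the Snf2h experiment. Trp63, the master transcription factor of stratified epithelium, gave −1.47 ± 0.24 (adjusted p = 0.0839) in Snf2h cKO eyes, with its other 2 probe sets at 0.02 and 0.11. Of 35 genes of corneal, conjunctival and skin epithelium, 0 were called over all genes and 1 fell adjusted over the list alone (mean −0.43 ± 0.35, camera adjusted p = 0.148). All 18 cornified skin and hair follicle markers, a list added after seeing the data, had negative changes (mean −1.08 ± 0.86, exact permutation p = 0.171), with wildtype replicate 3 far above the other arrays. The epithelium list passed without wildtype replicate 2 (adjusted p = 0.000343), cKO replicate 1 (0.0275) or cKO replicate 2 (0.0293), or with these 2 averaged (0.032). Of 35 genes of macrophages and other immune cells, 0 were called over all genes, and 2 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.324), with the lysosomal protease Lgmn at 1.16 ± 0.28 (adjusted p = 0.163) and the complement gene C1qa at 1.41 ± 0.43 (0.199). Lgmn had an adjusted p of 0.0127 without wildtype replicate 1, and the immune list passed without that array (0.0242) or cKO replicate 3 (0.014) and with array weights (0.0353). The red blood cell list (15 of 16 negative, camera adjusted p = 0.148) had 0 calls over all genes or adjusted over the list alone, and it passed without wildtype replicate 1 (0.0484) or cKO replicate 1 (0.0275).

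The lists for p53 targets, FGF and ERK targets, stress genes, retinal progenitors, pigment cells, skeletal muscle, endothelium, interferon response and sex-linked genes had 0 calls over all genes or adjusted over the list alone in Snf2h cKO eyes, and camera adjusted p values between 0.341 and 0.972. Of these, endothelium passed with the Xist level as a covariate (0.0197, median −0.36). The median, mean and camera direction differed in sign for lens transcription factors (median −0.09, mean 0.005, camera lower), mitosis (median −0.03, mean 0.02, camera higher) and cell cycle exit (median −0.05, mean 0.03, camera higher). They also differed for pigment cells (median −0.07, mean −0.06, camera higher), skeletal muscle (median −0.02, mean 0.03, camera higher) and the sex-linked genes (median 0.007, mean −0.09, camera lower).

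**Figure D1:**
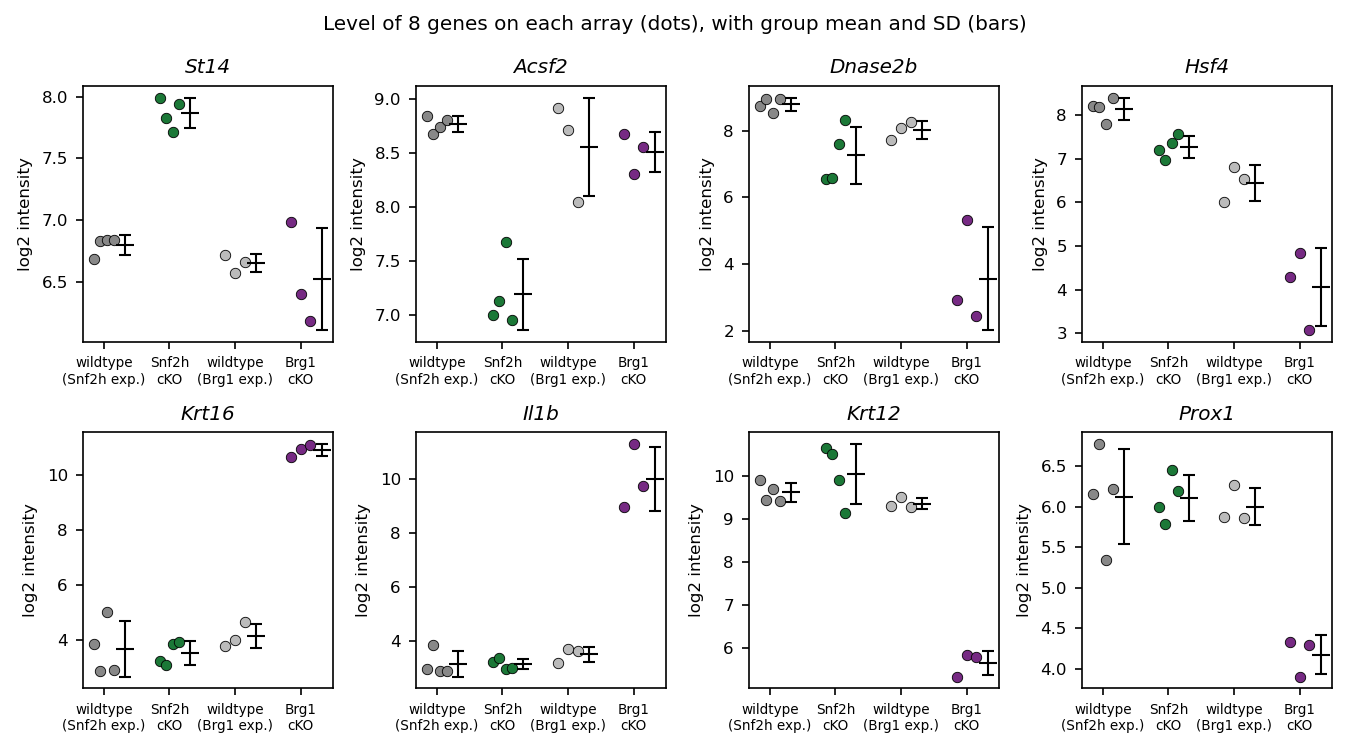
Log2 intensity of 8 genes on each of the 14 arrays (dots, by group), with the mean and SD of each group (bars). St14 is higher and Acsf2 lower in all 4 Snf2h cKO arrays than in their wildtype arrays, Krt16 and Il1b are higher and Krt12 and Prox1 lower in all 3 Brg1 cKO arrays than in theirs, and Dnase2b and Hsf4 are lower in the knockout arrays of both experiments.

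The comparison of Brg1 cKO with wildtype eyes gives the effect of a second remodelling ATPase at the same age. The keratin gene Krt16, the cornified envelope gene Sprr1b and the cytokine gene Il1b were among the 12 largest rises. Krt16, a keratin of wounded and hyperproliferative epithelium, rose 107-fold (log2 level 4.15 ± 0.44 to 10.89 ± 0.22, SD, n = 3 each; change 6.75 ± 0.25 SE, adjusted p = 0.000155). Il1b, the cytokine interleukin-1 beta, rose 88.9-fold (6.47 ± 0.54, adjusted p = 0.00336), and Mmp3, a matrix metalloproteinase, rose 54.7-fold (5.77 ± 0.30, 0.000347). The other 9 of the 12 largest rises were the neutrophil chemokine Cxcl2 (80.9-fold), Slfn4 (77.4), the lipopolysaccharide co-receptor Cd14 (55.9), the C-type lectin Clec4d (51.6), the cornified envelope gene Sprr1b (49.1), the acute phase gene Saa3 (45.4), the itaconate-producing enzyme Acod1 (36.7), the formyl peptide receptor Fpr2 (35.4) and the calprotectin gene S100a8 (32.2), with adjusted p values of 0.000327 to 0.0118. Each was higher in 3 of 3 knockout arrays than in any wildtype array. The wildtype levels of all 12 were dim (log2 2.16 for Sprr1b to 5.77 for S100a8, below the filter level of 6.77), and no background level came with the values, so these folds and their order are approximate.

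The largest falls in Brg1 cKO eyes included the corneal keratin Krt12 and the lens genes Dnase2b and Gja3. Krt12, the keratin of corneal epithelium, was 13.0-fold lower (9.35 ± 0.13 to 5.65 ± 0.28, SD, n = 3 each; change −3.70 ± 0.20 SE, adjusted p = 0.000347). Dnase2b was 21.9-fold lower (8.02 ± 0.28 to 3.57 ± 1.54; change −4.45 ± 0.68, adjusted p = 0.0312), and Gja3, a connexin of lens fibre gap junctions, was 7.43-fold lower (−2.89 ± 0.39, 0.0211). The other 9 of the 12 largest falls were Wfdc18 (32.9-fold lower), the tight junction gene Cldn8 (20.1), Ceacam10 (19.3), the epithelial transcription factor Ehf (12.3), the brush border myosin Myo7b (9.04), Calml3 (7.47), the alcohol dehydrogenase Adh1 (6.91), the carbonyl reductase Cbr2 (6.69) and the transcription factor Tfcp2l1 (6.66), with adjusted p values of 0.000347 to 0.0408. Each was lower in 3 of 3 knockout arrays than in any wildtype array. The knockout levels of all 12 were dim (log2 2.24 to 5.82), so these folds and their order are approximate too.

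In all, 76 genes rose and 59 fell in Brg1 cKO eyes, and in each of these 135 the groups did not overlap. At an unadjusted p under 0.05 there were 1142 genes, where 619.7 would be expected by chance, and the groups did not overlap in 14.5% of all genes, where chance gives 10%. Of the 12 largest rises, 9 passed in every fit that left out 1 array (all but Cxcl2, Acod1 and S100a8), and 2, 3 and 1 were lost without wildtype replicates 1, 2 and 3, and 2 without cKO replicate 3. Of the 12 largest falls, Krt12, Ehf and Myo7b passed in every such fit, and 8, 9 and 8 were lost without wildtype replicates 1, 2 and 3, and 3 and 8 without cKO replicates 1 and 3. The total was 30, 26 and 58 without wildtype replicates 1, 2 and 3, 45 without cKO replicate 3, 215 (98 higher and 117 lower) without cKO replicate 2, 23 with the filter on dim probe sets, and 0 with the unmoderated test. Without the Xist-low cKO replicate 1 there were 120 higher and 40 lower genes, and with the Xist level as a covariate, chosen after seeing the data, 105 higher and 30 lower.

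Lens genes were lower as groups in Brg1 cKO eyes. All 14 crystallins had negative changes, with 0 called over all genes and 12 lower adjusted over the list alone (mean −2.26 ± 0.86 SE between arrays, exact permutation p = 0.1, the smallest possible). The list passed with camera (adjusted p = 2.49e-13, or adjusted p = 0.444 with an estimated correlation). Crygs gave −3.73 ± 0.93 (12.59 to 8.85 ± 2.17 SD, adjusted p = 0.167), Crygn gave −3.65 ± 0.92 (0.17), Cryba2 gave −2.78 ± 0.67 (0.149) and Cryaa gave −1.34 ± 0.31 (0.14). The mean of the crystallins was −2.25, −0.78 and −3.75 relative to wildtype in cKO replicates 1, 2 and 3, and without replicate 2 these 4 genes passed (adjusted p = 0.00146, 0.0413, 0.00161 and 0.00714). Of 23 other fibre genes, 0 rose and 7 fell over all genes, and 1 rose and 10 fell adjusted over the list alone (median −0.25, mean −0.96 ± 0.31). The median was −0.53 without wildtype replicate 1, −0.59 without cKO replicate 2 and −0.41 with array weights. They passed with camera (adjusted p = 1.35e-07, or adjusted p = 0.444 with an estimated correlation). Prox1, a transcription factor of fibre differentiation, fell by 1.82 ± 0.20 on the log2 scale (adjusted p = 0.0102), and the RNA-binding gene Caprin2 fell by 2.17 ± 0.24 (0.0104). Mip fell by 2.28 ± 0.38 (0.0427), and Hsf4 gave −2.39 ± 0.44 (adjusted p = 0.0674, or 0.0217 without cKO replicate 2).

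Other lens lists gave smaller mean changes. Of 22 genes of organelle degradation and denucleation, 2 fell over all genes and 3 adjusted over the list alone, among them Dnase2b and Plaat3 (−1.85 ± 0.22, adjusted p = 0.013), a phospholipase of lens organelle degradation. Dnase2b is also in the fibre list. The organelle list did not pass (camera adjusted p = 0.108), though it did without wildtype replicate 2 (0.0452) or cKO replicate 2 (0.0402). Of 27 lens transcription factors, 1 fell over all genes and 2 adjusted over the list alone (mean −0.37 ± 0.08, camera adjusted p = 0.000543, or adjusted p = 0.297 with an estimated correlation), with Sox2 at −0.76 ± 0.21 (adjusted p = 0.234). The 1 that fell over all genes was Prox1, also in the fibre list. Of 20 lens epithelium genes, 0 were called over all genes or adjusted over the list alone (median −0.23, camera adjusted p = 0.00232, or adjusted p = 0.297 with an estimated correlation), with the Notch ligand Jag1 at −1.14 ± 0.34 (adjusted p = 0.273) and the cadherin Cdh1 at −1.07 ± 0.38 (0.418, or 0.0351 without cKO replicate 2). Of 36 mitosis genes, 0 were called over all genes or adjusted over the list alone and 32 had negative changes, such as Ube2c at −0.42 ± 0.17 (adjusted p = 0.52). The mitosis list passed with camera (adjusted p = 0.0013, or adjusted p = 0.74 with an estimated correlation) but not without cKO replicate 2 (adjusted p = 0.553, median 0.008). Caprin2 and Prox1 each passed in 4 of the 6 fits that left out 1 array, and Plaat3 in 2.

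Immune and interferon genes rose as groups in Brg1 cKO eyes. Of 35 genes of macrophages and other immune cells, 5 rose and 0 fell over all genes, and 20 rose adjusted over the list alone (mean 1.27 ± 0.31, exact permutation p = 0.1). The list passed with camera (adjusted p = 6.63e-19, or adjusted p = 0.444 with an estimated correlation). Besides Cd14, the leukocyte integrin Itgb2 rose by 2.64 ± 0.26 on the log2 scale (adjusted p = 0.00614), the leukocyte antigen Cd52 by 3.29 ± 0.38 (0.0109) and the chemokine Ccl4 by 3.84 ± 0.63 (0.0427). Of 26 interferon response genes, 1 rose over all genes and 9 adjusted over the list alone, and 26 had positive changes (mean 1.58 ± 0.74, camera adjusted p = 5.92e-13, or adjusted p = 0.461 with an estimated correlation). The antiviral GTPase Mx1 rose by 3.58 ± 0.28 (adjusted p = 0.00305), and Rsad2 gave 3.56 ± 0.66 (0.0644) and Irf7 1.84 ± 0.47 (0.18). The interferon list had means of 0.57, 2.92 and 1.25 relative to wildtype in cKO replicates 1, 2 and 3, and replicate 1 was the Xist-low array. Itgb2 and Mx1 passed in all 6 fits that left out 1 array, Cd52 in 4 and Ccl4 in 2 (0.0573 with quantile normalisation), while Rsad2 passed without wildtype replicate 3 (0.0219) and Irf7 without cKO replicate 2 (0.0485).

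Other tissue lists gave smaller or divided changes in Brg1 cKO eyes. Of 35 genes of corneal, conjunctival and skin epithelium, 2 rose (Krt16 and the cornified envelope gene Sprr1a, the latter by 4.62 ± 0.23, adjusted p = 0.000347) and 1, Krt12, fell, while adjusted over the list alone 4 rose and 8 fell. The list did not pass (camera adjusted p = 0.0587), though it did without cKO replicate 2 (0.000105) or 3 (0.0195), without wildtype replicate 3 (0.00994) and with the filter on dim probe sets (5.75e-05) or array weights (0.0412). The 23 endothelium genes had 0 calls over all genes or adjusted over the list alone (median 0.43, camera adjusted p = 0.0004, or adjusted p = 0.626 with an estimated correlation), with Esm1 at 1.24 ± 0.44 (adjusted p = 0.406). The 38 skeletal muscle genes also had 0 calls over all genes or adjusted over the list alone (median 0.26, camera adjusted p = 0.0231, or adjusted p = 0.743 with an estimated correlation), with the troponin Tnnt2 at 0.69 ± 0.26 (adjusted p = 0.435). The endothelium median was 0.67 without cKO replicate 1, and the muscle median was 0.67 without wildtype replicate 3 and 0.75 without cKO replicate 1. Without cKO replicate 2 the endothelium list did not pass (0.0929, median 0.20) and the muscle median was −0.065 (0.658), and the muscle list did not pass without wildtype replicate 1 (0.397) or 2 (0.208), without cKO replicate 3 (0.228) or with the filter on dim probe sets (0.0536). Of the remaining lists, 0 passed and 0 had genes called over all genes, and adjusted over the list alone 1 stress gene, Junb (0.95 ± 0.18, adjusted p = 0.0674 over all genes), rose. Leaving out cKO replicate 2 brought 3 of these past the threshold, namely photoreceptors (0.000169), stroma (0.022) and red blood cells (0.00561). Without cKO replicate 1 these were DNA replication (0.0224), stress genes (0.00918) and retinal progenitors (0.00918). With the Xist level as a covariate these 3 (0.0168, 0.00487 and 0.00784) and stroma (0.0174, median 0.23, against −0.13 without cKO replicate 2) passed, and red blood cells passed with array weights (0.0302). Stress genes also passed without wildtype replicate 3 (0.0158), and chromatin subunits without wildtype replicate 2 (0.0354) or cKO replicate 3 (0.0138). For p53 targets the median was 0.03 and the mean 0.02 while camera's direction was lower (adjusted p = 0.734).

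**Figure D2:**
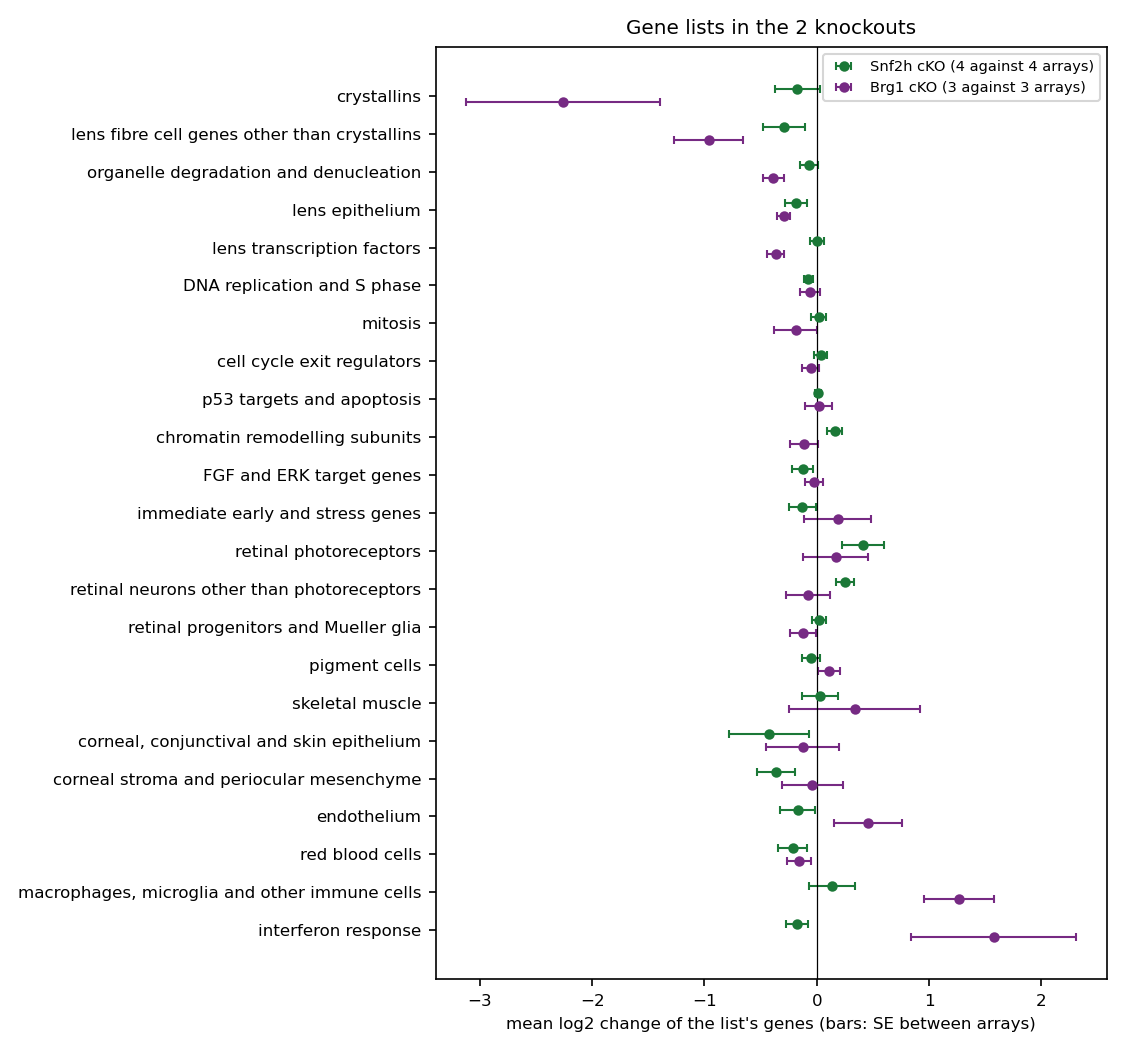
Mean log2 change of each gene list other than the sex-linked genes in Snf2h cKO (4 against 4 arrays) and Brg1 cKO eyes (3 against 3), with bars for the SE between arrays. Crystallins have a mean of −0.17 in Snf2h cKO and −2.26 in Brg1 cKO eyes, and photoreceptors have 0.41 in Snf2h cKO eyes.

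The interaction asked which genes changed differently in Snf2h cKO and in Brg1 cKO eyes. It called 115 genes, of which 14 had a higher and 101 a lower log2 change in Snf2h cKO than in Brg1 cKO eyes (1492 at an unadjusted p under 0.05). The experiments also differ in background, and the cells of Brg1 deletion are not given. These differences therefore cannot be assigned to the ATPase that was lost. The 6 largest negative differences were in genes that rose in Brg1 cKO eyes, namely Cxcl2 (−6.91 ± 0.77 SE, adjusted p = 0.000305), Krt16 (−6.88 ± 0.60), Slfn4 (−6.60 ± 0.56), Il1b (−6.49 ± 0.58), Clec4d (−6.41 ± 0.55) and Mmp3 (−6.39 ± 0.40). The 6 largest positive differences were Krt12 (4.12 ± 0.42, adjusted p = 0.000111), the limbal keratin Krt15 (3.18 ± 0.68, 0.0438), Gja3 (3.03 ± 0.59, 0.0233), Ceacam10 (3.02 ± 0.64, 0.0415), Calml3 (2.85 ± 0.54, 0.0203) and the phosphate transporter Slc34a2 (2.55 ± 0.34, 0.00151). The effects on St14 (1.20 ± 0.24, adjusted p = 0.0307) and Acsf2 (−1.53 ± 0.31, 0.0288) also differed. Dnase2b (2.92 ± 0.79, adjusted p = 0.139) and Hsf4 (1.52 ± 0.47, 0.196) did not pass the test of a difference. With the Brg1 arrays in their real groups, 12 of the 70 splits of the Snf2h arrays gave as many genes (highest 209), so the count does not show that the Snf2h grouping contributes to it. It was 13 with the filter on dim probe sets and 68 without wildtype replicate 1 of the Brg1 experiment. All 6 negative differences and those of Krt12 and Slc34a2 passed in all 14 fits that left out 1 array, while Krt15 and Ceacam10 passed in 2 of them, Gja3 in 10 and Calml3 in 11. With Snf2h cKO replicates 1 and 2 averaged, Krt15 (0.0947) and Ceacam10 (0.0678) did not pass, nor did Krt15 with quantile normalisation (0.0562).

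Shared responses were mostly among genes lower in both knockouts, at an unadjusted p. By limma's adjusted p, 0 genes changed in the same direction in both knockouts. At an unadjusted p under 0.05, 110 genes were lower in both, against 40.2 expected (one-sided Fisher exact test p = 1.95e-23, which treats genes as independent although they are not), and 48 were higher in both, against 56.1 expected. In opposite directions, 71 were lower in Snf2h cKO and higher in Brg1 cKO eyes (58.2 expected), and 24 were the reverse (38.8 expected). Of the 59 genes that fell in Brg1 cKO eyes, 52 had negative changes in Snf2h cKO eyes (median −0.64) and 22 of them passed an unadjusted p under 0.05, while of the 76 that rose 55 had negative changes (median −0.16). Across all genes the log2 changes had a Pearson correlation of 0.0871 and a Spearman correlation of 0.0711, and across the 23 fibre genes other than crystallins these were 0.55 and 0.344. Across the 14 crystallins they were 0.115 and 0.103, and genes are not independent replicates. The count of shared genes by adjusted p was 1 with the filter on dim probe sets, 1 without wildtype replicate 1 of the Snf2h experiment, and 16, all lower, with array weights in both fits, an alternative chosen after seeing the data.

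**Figure D3:**
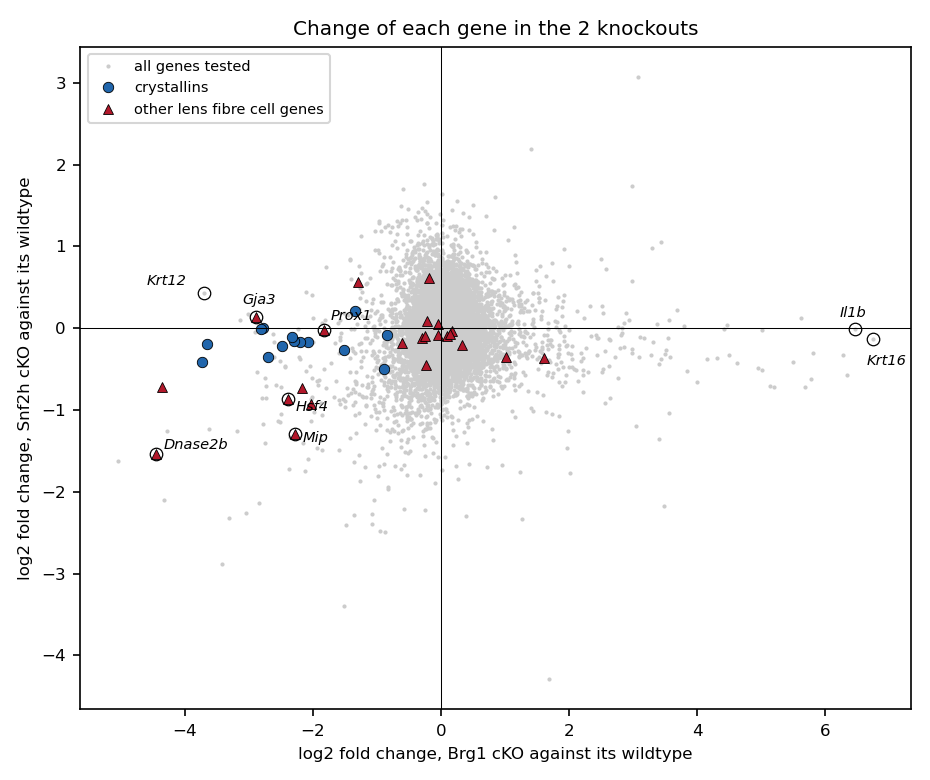
Log2 fold change of each gene tested in Brg1 cKO (horizontal axis) and Snf2h cKO eyes (vertical axis), each against its own wildtype arrays, with crystallins as blue circles, other lens fibre genes as red triangles and 8 genes named. Dnase2b lies at −4.45 and −1.53, and Krt16 and Il1b lie far to the right with little change in Snf2h cKO eyes.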

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

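The counts over other splits of the samples were planned. Chosen only after the result was seen were the splits and the muscle comparison with the near-identical arrays averaged, the splits with the Brg1 groups kept, and the tests of skin tissue, sex make-up, resident macrophages, wildtype replicate 3, RNA quality, surrounding tissue, lens share and bright probe sets.

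The effect of the 2 knockouts differed in 115 genes by the interaction test, which cannot tell the ATPase lost from the background of the 2 experiments. Of 100 splits drawn from 700, 1, the real one, gave as many (highest other 103), but only 7 other drawn splits kept the Brg1 groups. With the near-identical Snf2h cKO replicates 1 and 2 averaged, 3 of 100 gave as many as the real 84 (highest other 88). The grouping of the Brg1 arrays carries these counts, since the drawn splits of all arrays that regrouped them gave at most 8 genes. The 10 splits of the Brg1 arrays are too few for a share under 0.05, so the drawn splits do not exclude chance. With the Brg1 groups kept, 12 of all 70 splits of the Snf2h arrays gave as many (highest other 209), and 10 of 35 with the pair averaged (highest other 144), so chance cannot be excluded for the part of the Snf2h grouping. Of the 35 splits of the Snf2h experiment, 1, the real one, gave its 2 genes and the highest other gave 0. That share cannot exclude chance, since it treats the near-identical replicates as independent. With them averaged the real count was 0, which any split must match (35 of 35), so that test says nothing of chance, though the highest other count of 32, with wildtype replicate 1 grouped with the knockout samples, points to structure among the samples. For the Snf2h gene lists 25 of 35 splits gave as many as the real 4, with a highest other of 10, so chance cannot be excluded there. The 10 splits of the Brg1 experiment are too few for a share under 0.05. Of these 1 gave as many as the real 135 genes (highest other 1), and 7 gave as many as its real 9 lists (highest other 14).

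In Brg1 cKO eyes, Krt16, Sprr genes and inflammatory genes rose far above wildtype. Skin left on the knockout eyes would raise all cornified skin and hair follicle markers alike, but their median change was 0.221 (SE 0.157), and Krt1 and Krt10 (wildtype log2 levels 7.07 and 7.65, not comparable between probe sets) gave −0.53 and −0.40 (3 of the 18 are also in the fixed epithelium list). An unequal sex make-up as the whole cause is argued against by the Xist-high arrays alone, which called 120 genes higher, against at most 1 per direction in the other splits of those 5 arrays. More of the resident macrophages, in an unaltered state, would raise their markers as far as the pattern, but these changed by 0.291 on average (SE 0.229), Csf1r and C1qb reaching log2 levels of 9.43 (12 of 12 are also in the fixed immune list). Activated macrophages, incoming neutrophils, infection, litter and the tissue of Brg1 deletion stay open.

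Photoreceptor genes were higher and stromal genes lower as groups in Snf2h cKO eyes. Wildtype replicate 3 alone is argued against as the source of the mean changes. Without it they were 0.456 for photoreceptors and −0.33 for stroma, against 0.411 and −0.367 over all arrays. Camera still called both lists without that array (larger adjusted p = 0.000894) and with the Xist level as a covariate (1.08e-05). In 25 of 35 splits camera called as many lists as in the real one, so these calls cannot decide on sex make-up, which stays open. RNA quality was tested with the Gapdh 3' minus 5' difference as a covariate. Camera called both lists with it, over all arrays and without wildtype replicate 3 (largest adjusted p = 0.0238). Without that array the covariate moved the photoreceptor mean from 0.456 to 0.948 and the stroma mean from −0.33 to −0.375. The difference separates the groups, so this covariate cannot tell RNA quality from the knockout, and RNA quality stays open. Less tissue of every kind around the eye would lower muscle and stroma alike, and is argued against over all arrays, where the mean change of muscle exceeded that of stroma by 0.398 (SE 0.109, exact permutation p = 0.0286), but with the near-identical arrays averaged the gap was 0.397 (exact permutation p = 0.0571) and it cannot be told apart from a loss of stroma. Less tissue other than muscle cannot be told apart from such a loss either, since endothelium exceeded stroma by 0.197 (SE 0.0695, exact permutation p = 0.0571) and surface epithelium had a mean of −0.43, while more retina per eye and litter stay open as untested and chance cannot be excluded (25 of 35 splits).

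Crystallins were lower as a group in Brg1 cKO eyes. A lower share of lens RNA in the knockout eyes would move all crystallins alike, and 0 of 14 departed from their mean change in Brg1 cKO eyes at an adjusted p under 0.05. With relative changes from −1.48 ± 0.40 (Crygs, adjusted p = 0.0993) to 1.42 ± 0.50 (Cryba1, 0.144), a shared loss and a gene-specific one cannot be told apart for the crystallins with 3 arrays per group. Compression of the brightest probe sets was tested by the Spearman correlation of wildtype level with change over the crystallins, which was 0.235 (permutation p = 0.42, 100000 permutations), and with wildtype log2 levels spanning 11.01 to 13.82 it cannot be told apart from an even change. A smaller lens and lower transcription per cell were not tested and stay open.

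The Snf2h wildtype and cKO groups were checked for outlying arrays in 144 sets, each 1 measure on the 4 arrays of 1 group. In 12 sets an array lay far from the other 3, where chance gives about 7.2. Measures such as Mip and the fibre list that holds it are related, so these sets are not independent. Wildtype replicate 3 of the Snf2h experiment stood apart in 5 of the 12. Its Gapdh 3' minus 5' difference was 4.47 (others 1.09 to 1.46), its fibre list mean was −0.29 (0.06 to 0.14), its cell cycle exit list mean was −0.15 (0.04 to 0.06), its Crygs level was 12.58 (12.89 to 12.96) and its Mip level was 9.96 (10.75 to 10.91). Wildtype replicate 4 was lowest in the lens epithelium list at −0.20 (others 0.05 to 0.09). Wildtype replicate 2 was highest for Smarca5 1424206_at at 9.82 (9.34 to 9.36). Wildtype replicate 1 was lowest for Crygf at 12.58 (12.83 to 12.86) and for St14 at 6.68 (6.83 to 6.84). Snf2h cKO replicate 4 was highest in the photoreceptor list at 0.89 (0.21 to 0.33) and for Ifit1 at 4.13 (2.86 to 2.98), and cKO replicate 1 was highest for Trem2 at 5.71 (5.32 to 5.38).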

How the results depend on the processing

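Averaging the near-identical cKO replicates, the Xist covariate, array weights for the shared genes and all alternatives for the genes lower in both knockouts at an unadjusted p were chosen after seeing the data, and the other alternatives here were planned. Where no reason is given, the cause was not tested.

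In Snf2h cKO eyes the 2 called genes (1 higher, 1 lower) became 1 (0 higher, 1 lower) with quantile normalisation of all arrays, 2 (0 higher, 2 lower) with it within each experiment, 7 with trended robust eBayes, 230 (136 higher, 94 lower) with array weights, 4 with the Xist covariate, 4 with 1 fit over all arrays, and 0 with cKO replicates 1 and 2 averaged, with or without array weights. These replicates had array weights of 3.70 and 4.22, against 0.374 to 0.939 for the other 6 arrays, and with the pair averaged the weighted count was 0. With the filter on dim probe sets, which tests fewer genes, the count was 13. In Brg1 cKO eyes the 135 genes became 23 with the filter on dim probe sets, 209 with array weights, 260 with 1 fit over all arrays and 0 with the unmoderated test. The Xist covariate also called 135 genes, 94 of them shared with the original 135, but with 105 higher and 30 lower in place of 76 and 59, and without the Xist-low cKO replicate 1 there were 120 higher and 40 lower. The 115 interaction genes became 13 with the filter and 174 with array weights. The 0 shared genes became 1 with the filter and 16 with array weights. The replicate number as a block gave 0 genes in Snf2h cKO, 49 in Brg1 cKO eyes and 79 in the interaction. Equal numbers gave no sign of pairing, since the knockout array of the same number was the most alike for 1 of 4 and 0 of 3 wildtype arrays. With so few arrays pairing cannot be excluded.

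The Snf2h lists past the threshold went from 4 to 0 with an estimated correlation, 0 with fry and 7 with array weights, and the Brg1 lists went from 9 to 0 with an estimated correlation and 0 with fry. Of single named genes, quantile normalisation ended the calls of St14, Ccl4 and the interaction of Krt15, while trended robust eBayes ended 0 and added 3 in Brg1 cKO eyes. Leaving out 1 array at a time gave 0 to 60 Snf2h genes, 26 to 215 Brg1 genes, 68 to 162 interaction genes, 0 to 1 shared genes, 3 to 6 Snf2h lists and 8 to 12 Brg1 lists. Over these fits the sign changed for Smarca5 1424206_at (−0.344 to 0.059, positive without Snf2h cKO replicate 3), Smarca4 1426804_at (−0.138 to 0.211, negative without Brg1 cKO replicate 1) and the muscle list median in Brg1 cKO eyes (−0.065 to 0.752, negative without Brg1 cKO replicate 2).

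The 110 genes lower in both knockouts at an unadjusted p were 82 to 135 without 1 array (1.99 to 3.36 times the expected number) and 53 with the filter, which tests fewer genes. Quantile normalisation of all arrays moved the median of all genes from −0.05 to −0.04 in Snf2h cKO and from 0.02 to 0.03 in Brg1 cKO eyes. Signal over background limits dim genes, whose changes are compressed.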

Other observations

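The marker lists for wound keratinocytes, neutrophils, resident macrophages and lymphocytes, and the array weights for shared genes, were chosen only after the result was seen.

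In Brg1 cKO eyes 13 of 17 keratinocyte genes of cornification and wound repair rose over all genes. This list was drawn up after the result and holds genes that prompted it, such as Krt16 and Sprr1b, so its count is no independent test, and 0 of the 18 cornified skin and hair follicle markers were called. Members not named so far include Dmkn (3.49 ± 0.22, adjusted p = 0.000747), Sprr2d (3.31 ± 0.36, 0.0097) and Krt6b (2.98 ± 0.34, 0.0109), and 4 of the 17 are also in the fixed lists. In Snf2h cKO eyes the list had a mean of −0.34 ± 0.38 (SE between arrays). Of 14 measured neutrophil genes, 2 rose in Brg1 cKO eyes, S100a8 and S100a9 (4.48 ± 0.41, adjusted p = 0.00502), and both are also made by keratinocytes. The mean of the neutrophil list was 1.66 ± 0.57 (exact permutation p = 0.1, the smallest possible for 3 against 3), or 1.14 ± 0.57 over the 12 genes without these, which exceeded the resident macrophage genes by 0.85 ± 0.42. Among these 12, Il1r2 gave 3.38 (adjusted p = 0.0841), Trem1 2.76 (0.106), Cxcr2 1.95 (0.419), Csf3r 1.57 (0.181) and Mmp9 0.95 (0.894). Trem1 and Cxcr2 had dim probe sets, at wildtype log2 levels of 2.16 and 2.51. Of the granule genes, Mmp8 gave 1.01, Ngp 0.96, Lcn2 0.94, Camp 0.67 and Ltf −0.47, while Elane (−0.02) and Mpo (−0.01) had dim probe sets, at wildtype log2 levels of 2.31 and 2.20. Resident macrophage genes, 12 of them, had a mean of 0.29 ± 0.23 (exact permutation p = 0.2). Of 13 lymphocyte genes, 1 rose, the interleukin receptor Il7r (3.28 ± 0.39, adjusted p = 0.0118), while the other 12 gave −0.24 to 0.40 with a mean of 0.11 ± 0.08 (0.35 ± 0.08 over all 13). In Snf2h cKO eyes the means were −0.13 for neutrophil, 0.16 for resident macrophage and −0.31 ± 0.11 (exact permutation p = 0.0571) for lymphocyte genes.

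With array weights in both fits, 16 genes were called lower in both knockouts, against 0.721 expected, and 0 higher, against 1.25 expected. With the near-identical Snf2h cKO replicates 1 and 2 averaged, array weights gave 0 Snf2h calls, so 0 of the 16 were then shared. The 16 were Aox4, Ceacam10, Celsr1, Dnase2b, Dock5, Ell2, Hsf4, Htr3a, Myo7b, Scgn, Slc15a1, Tent5c, Trpc6, Upk3b, Vit and Wnt7b. Called in opposite directions were Ereg (−1.12 in Snf2h cKO and 3 in Brg1 cKO eyes), U90926 (−0.78 and 1.03) and Pnoc (0.61 and −1.16). Dnase2b and Hsf4 act in fibre cell maturation, and Wnt7b is a Wnt ligand. The weights favour the near-identical Snf2h cKO replicates 1 and 2, whose fibre list means of −0.55 and −0.58 were the lowest of that experiment.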
